A study of Saccharomyces cerevisiae with 18 samples.

How the data were processed

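The series holds 18 yeast libraries, of which 14 were analysed here: 7 ribosome footprint and 7 rRNA-depleted mRNA-Seq libraries. Wild type (WT), the dhh1 deletion strain (KO) and the strain with a Dhh1 plasmid (OE) each had 2 biological replicates per kind of library, and the strain with the same plasmid coding for the catalytically inactive Dhh1-DQAD protein (DQAD) had 1 library per kind. All cells were in the BY4741 background and harvested at an OD of 0.4. Per the labels' protocols, WT and KO carried no plasmid and grew in rich medium (YPD), whereas OE and DQAD carried a pAG425-GPD plasmid and grew in dropout medium, so OE against WT compares Dhh1 level, plasmid and medium together. Footprints of 25 to 34 nt were taken in replicate 1 of each group and of 15 to 34 nt in replicate 2 and in the DQAD library; mRNA fragments had 20 to 40 nt. The other 4 columns of the tables, which belong to the reporter experiment, could not be tied to 1 sample each by name and were not used. The designs fixed before the data were examined named 9 libraries per kind and 18 in the joint model; without those columns, 7 and 14 entered.

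Per the submitters' processing notes, the authors used CASAVA 1.8, cutadapt 1.7.1 and Bowtie 1.1.2 with the sacCer3 build; the counting tool, its use of strand and its treatment of reads that map to several places are not given in the sources used here. The authors deposited a table of raw read counts per open reading frame (ORF) and a table of RPKM values. The kind of library and the replicate of each column were read from its name, matched to the sample titles; no key to the names is given in the sources used here. The counts were whole numbers that differed in sum between libraries, and they were used without change. The deposited RPKM values scale the same counts by coding length and by a library total that was 1.48 to 2.1 times the count sum for mRNA and 1.01 to 1.03 times for footprints. The length behind the RPKM of an ORF was the same in all libraries to within a relative spread of 1.2e-11; over 6383 ORFs with a length, 100.0% were multiples of 3 and 94.8% equalled the span in the RefSeq annotation, so they are coding lengths. Of 6685 ORFs, 6006 matched a RefSeq R64 locus tag and took its symbol and 1-based coordinates; the 679 others held 0.291 to 0.988% of the counts of a library.

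Library totals were 3465526 to 8667764 counts for mRNA and 11449979 to 65905563 for footprints. A floor of 3 counts corresponds to 0.346 to 0.866 CPM, a count as a share of its library total, in the mRNA libraries and to 0.046 to 0.262 CPM in the footprint libraries. Reads carried no molecular identifiers in the sources used here, so floors and counting intervals cover counting error only. A fold against a group with 0 counts was computed against 3 counts over the group and is given as a bound; with 1 to 3 counts, the ratio of pooled counts is given with an exact Poisson interval at 95%. For footprint to mRNA ratios with several such counts, the limits were combined at their extremes. The replicate pairs were compared by chi-square over genes with a count of at least 20.

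Each comparison used edgeR's quasi-likelihood test (version 4.0.16, R 4.3.3) with TMM factors, the filterByExpr filter on the group and Benjamini-Hochberg adjustment over all tested genes, with a threshold of 0.05. The mRNA and footprint comparisons were fitted over the 7 libraries of their kind, leaving 3 residual degrees of freedom. Translational efficiency, the footprint to mRNA ratio of a gene, was tested as the interaction of group and library kind in 1 model over the 14 libraries, with 6 residual degrees of freedom. The DQAD libraries have no replicate and were assumed to vary like the duplicated groups. Standard errors (SE) are the fitted log2 fold change divided by the square root of the F statistic. The comparisons were KO against WT, OE against WT and DQAD against OE, each for mRNA, footprints and translational efficiency.

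Gene lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the 24 lists of a comparison (216 tests over 9 comparisons), and again with an estimated correlation. The lists were cytosolic ribosomal proteins, mitochondrial ribosomal proteins, ribosome biogenesis, translation factors, mRNA decay factors (decapping, deadenylation and decay from the 5' end), glycolysis and fermentation, respiratory chain and ATP synthase, TCA and glyoxylate cycle, stress response, amino acid biosynthesis, sulfur and methionine, purine and one-carbon, phosphate regulon, iron regulon, hexose transport and galactose use, mating and pheromone response, histones, autophagy, proteasome, ergosterol synthesis, meiosis and sporulation, thiamine and vitamin B6, cell wall and cell surface, and nitrogen catabolite genes. Per list, the number of members past the threshold is given over all genes and adjusted over the list alone. The lists, the tests, the alternatives and the rule for named genes were chosen before the data were examined; exceptions are stated where they occur. The rule took, per mRNA or footprint comparison, the 8 largest rises and 8 largest falls (6 each for translational efficiency) among genes past the threshold whose libraries did not overlap and which had a mean of at least 10 CPM, then the 3 members with the lowest adjusted p of each list called; the text names a part of them. Genes with a near-identical copy, or that overlap another gene, are called uncertain where named, since the counting of shared reads is not stated.

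The tests were run first on simulated counts with the means and library sizes of these libraries and a set of genes changed by known folds. For KO against WT, 61.0% of the 2-fold changes and 89.0% of the 4-fold changes in mRNA were recovered over 5654 genes, 81.8% and 92.0% in footprints over 5752 genes, and 31.3% and 87.0% in translational efficiency over 5778 genes. For OE against WT, the values were 50.0% and 87.0% over 5653 genes, 73.0% and 92.0% over 5744 genes, and 28.3% and 81.0% over 5776 genes. For DQAD against OE, they were 42.3% and 90.9% over 5646 genes, 72.4% and 89.9% over 5736 genes, and 12.6% and 64.6% over 5775 genes. Of the calls made on simulated counts, 2.2 to 8.5% were false.

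Alternatives were RLE size factors, no filter on low counts, DESeq2 (version 1.42.0), a replicate block, the compared groups only, limma-trend on log2(RPKM + 1) for ORFs with an RPKM of at least 1 in 2 libraries, and leaving out each library in turn; a fit without the DQAD libraries, a split of the WT libraries and the hexose list without its GAL1, GAL2, GAL3, GAL7 and GAL10 genes were added after the data were seen. Replicates 1 and 2 of the groups were treated as paired because the labels give each footprint number a shared fragment range and all correlations of same-numbered deviations lay at 0.1 or above (0.143, 0.381 and 0.16 for mRNA; 0.355, 0.125 and 0.1 for footprints). For comparisons that share the WT libraries, 20 sets of unchanged groups were simulated against them. Relations across genes were computed for coding length, WT mRNA level and WT footprint to mRNA ratio; codon optimality was not analysed here because no coding sequences were used. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and plots.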

Results

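Ribosome footprints and mRNA were sequenced from yeast cultures that lacked Dhh1, had wild-type Dhh1, or overproduced active or catalytically inactive Dhh1. Dhh1 is a DEAD-box RNA helicase that promotes decapping and represses translation, and the series asks how its loss and its excess alter mRNA levels and ribosome occupancy. The mRNA libraries held 7028598 and 3475294 counts in WT, 7174784 and 4314308 in KO, 8431685 and 3465526 in OE and 8667764 in DQAD. The footprint libraries held 44411127 and 11449979 counts in WT, 64369735 and 38841122 in KO, 65905563 and 27240816 in OE and 15855689 in DQAD. The 10 most abundant ORFs took 11.72 to 19.87% of a library. Replicates were close but not identical: Pearson r across genes (not independent replicates) of log2 CPM within a group was 0.983 to 0.999, and the chi-square per degree of freedom between the libraries of a pair was 12.4 to 118.3, so no pair was one library counted again.

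DHH1 (YDL160C, chromosome IV, 170410 to 171930) followed the labels in mRNA, and in footprints for KO, whereas its footprint rise in OE was not called. Its mRNA stood at 239.3 and 385.8 CPM in the WT libraries, at 0.317 and 5.96 CPM in KO (3 and 31 counts), at 1716 and 2204 CPM in OE and at 1211 CPM in DQAD. Footprints on DHH1 stood at 254.8 and 255.4 CPM in WT, 0.0496 and 0.615 CPM in KO (3 and 22 counts), 420.4 and 326.2 CPM in OE and 330.7 CPM in DQAD. In KO, DHH1 mRNA fell by 6.93 on the log2 scale (SE 0.56, n = 2 per group, edgeR adjusted p = 1.45e-06) and its footprints fell by 9.85 (SE 0.61, edgeR adjusted p = 0.000118). In OE its mRNA rose by 2.65 (SE 0.40, edgeR adjusted p = 0.000242), a call that DESeq2 did not make. There the change in footprints, 0.55, did not pass (edgeR adjusted p = 0.243), nor did that in translational efficiency, −2.08 (edgeR adjusted p = 0.0681). DQAD and OE did not differ detectably in DHH1 mRNA (−0.69, edgeR adjusted p = 0.421) or footprints (−0.18, edgeR adjusted p = 0.778).

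LEU2, a leucine synthesis gene that BY4741 lacks and pAG425 plasmids carry, had 2958 and 2477 CPM of footprints in OE and 1687 CPM in DQAD, against 2.38 and 3.20 CPM in WT and 1.95 and 3.88 CPM in KO. Its mRNA did not follow that order: WT held 919 and 307 CPM, KO 47.3 and 27.9, OE 2267 and 1396, and DQAD 855 CPM. URA3, also missing in BY4741, had 103.1 and 42.0 CPM of mRNA in WT with 0.486 and 0.700 CPM of footprints, but 10.6 and 4.89 CPM of mRNA in OE with 12.9 and 14.6 CPM of footprints. GAL1, the galactokinase gene (uncertain because a noncoding RNA gene overlaps it), had 823 and 320 CPM of mRNA in WT with 39.6 and 29.9 CPM of footprints, and 13560 and 11220 CPM of mRNA in OE with 17640 and 11130 CPM of footprints. In DQAD, GAL1 had 5039 CPM of mRNA and 18.7 CPM of footprints. Of the mating type markers, MATALPHA1 and HMLALPHA1 had 0 counts in all 14 libraries; markers of alpha cells summed to 13.1 to 23.1 CPM of mRNA and those of a cells to 1020 to 1530 CPM, as for a culture of mating type a.

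**Figure D1:**
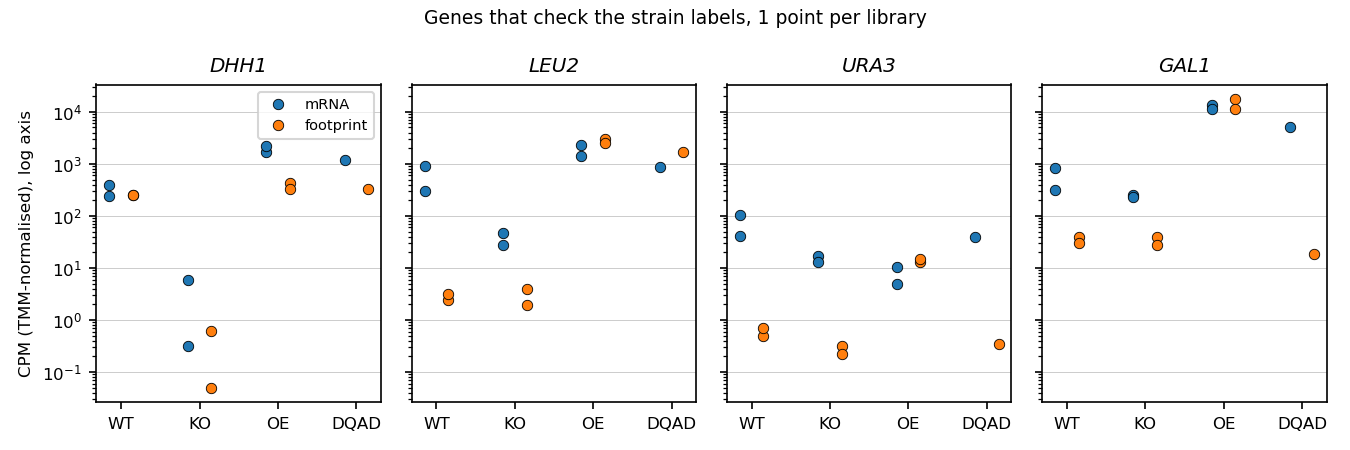
CPM (log axis, TMM-scaled) of DHH1, LEU2, URA3 and GAL1 in each library of WT, KO, OE and DQAD, with mRNA in blue and footprints in orange, 1 point per library. DHH1 lies lowest in KO in both kinds of library, and GAL1 in DQAD has 5039 CPM of mRNA and 18.7 CPM of footprints.

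KO against WT asks what loss of Dhh1 does to mRNA levels. Among the largest rises, HSP30, a plasma membrane heat shock protein, rose by 4.70 on the log2 scale (SE 0.32, n = 2 per group, edgeR adjusted p = 1.84e-07), RGI1, a respiratory growth gene, by 4.36 (SE 0.26) and CYC7, a cytochrome c isoform of low-oxygen growth, by 3.72 (SE 0.44). FIT3, a cell wall protein of iron uptake, fell by 2.50 (SE 0.25), and ARG1, an arginine synthesis enzyme, fell by 2.33 (SE 0.34). GAL2, the galactose permease, fell by 2.88 (SE 0.37, edgeR adjusted p = 0.000101), against WT libraries with galactose gene mRNA (GAL2 at 1232 and 430.5 CPM) without footprints to match. Of 5715 genes tested, 531 rose and 537 fell, 321 and 159 of them by at least 2-fold; without KO mRNA replicate 1 the total was 391 and without KO mRNA replicate 2 it was 239. Of the calls, 49.7% were rises, against 71.5% on log2(RPKM + 1), where the median of all genes lay at 0.28.

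Cytosolic ribosomal protein mRNAs fell as a group in KO: 100 of 137 fell, none rose and 37 did not pass (0 up and 123 down adjusted over the list alone), with a median log2 fold change of −0.73 (camera adjusted p = 6.42e-36, adjusted p = 0.378 with estimated correlation). Translation factor mRNAs went the same way, with 19 of 38 lower and none higher (0 and 26 over the list alone), among them the poly(A)-binding protein PAB1 (−1.57, SE 0.23), the initiation factor SUI1 (−1.15) and HCR1 (−1.27); their median was −0.60 (camera adjusted p = 5.40e-11, adjusted p = 0.304 with estimated correlation). In the stress response list, 30 of 51 members rose and 1 fell (32 and 2 over the list alone), with a median of 1.18 (camera adjusted p = 1.23e-23, adjusted p = 0.278 with estimated correlation). Its members with the lowest adjusted p included GSY2, a glycogen synthase (1.92), and TSL1 of trehalose synthesis (1.86). Glycolysis and fermentation had 10 of 20 members lower and 1 higher (13 and 1 over the list alone, median −0.75, camera adjusted p = 4.83e-06, adjusted p = 0.486 with estimated correlation); the riser was GLK1, a glucokinase (1.49, uncertain because of an overlapping ORF). Ergosterol synthesis, the yeast sterol pathway, had 14 of 28 lower and none higher (17 and 0 over the list alone), such as NCP1 (−1.41), ERG13 (−1.29) and ERG6 (−1.11). The median was −0.59 (camera adjusted p = 1.80e-08, adjusted p = 0.278 with estimated correlation).

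Amino acid biosynthesis showed 18 of 66 members lower and 1 higher in KO mRNA (21 and 3 over the list alone), with LYS21 of lysine synthesis (−1.69) and glutamine synthetase GLN1 (−1.58) among the falls. The median was −0.28 (camera adjusted p = 4.83e-06, adjusted p = 0.304 with estimated correlation). Genes of purine and one-carbon metabolism had 8 of 20 lower and 1 higher (8 and 2 over the list alone, median −0.40, camera adjusted p = 0.00826), and the riser was GCV1 of the glycine cleavage complex (1.69); GUA1 of GMP synthesis was among the falls (−1.17). That list had an adjusted p = 0.304 with estimated correlation. Mitochondrial ribosomal proteins had 9 of 69 higher and none lower (6 and 0 over the list alone, median 0.33, camera adjusted p = 0.00179, adjusted p = 0.348 with estimated correlation). The autophagy list, with 5 of 39 higher and none lower (4 and 0 over the list alone) and ATG41 among them (2.21), had a median of 0.34 and a camera adjusted p = 0.0191 (adjusted p = 0.304 with estimated correlation), and was not called without KO mRNA replicate 1 (camera adjusted p = 0.099). The iron regulon, with 8 of 29 lower and 1 higher, did not pass (camera adjusted p = 0.0597), but was called downward with the replicate block (0.0492) or RLE size factors (0.0492).

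Footprints answer whether ribosome occupancy moved in the same genes in KO. Among the largest rises, TIR2, a cell wall mannoprotein, rose by 6.26 on the log2 scale (SE 0.41, n = 2 per group, edgeR adjusted p = 0.000132), EGO4 by 4.95 (SE 0.29) and RTN2, a reticulon-like membrane protein, by 4.61 (SE 0.21). The cell wall mannoprotein of iron uptake FIT1 fell by 4.34 (SE 0.67), and YEH1, a steryl ester hydrolase, fell by 1.90 (SE 0.20). Of 5789 genes tested, 1215 rose and 996 fell, 401 and 176 of them by at least 2-fold. Without KO footprint replicate 1 the total was 903 against 2211; the other 3 left-out libraries moved it too, to 1448 without WT footprint replicate 1, 1241 without WT footprint replicate 2 and 1216 without KO footprint replicate 2.

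In the stress response list 44 of 51 members rose in KO footprints and none fell (45 and 0 over the list alone), with a median log2 fold change of 1.90, such as DDR2 (4.15, SE 0.18) and the glycogen debranching enzyme GDB1 (2.61) (camera adjusted p = 2.36e-46), and the respiratory chain and ATP synthase had 33 of 39 members higher and none lower (37 and 0 over the list alone), among them CYC7 (4.15, SE 0.19) and QCR10 of complex III (1.74). The median was 0.90 (camera adjusted p = 5.23e-12, adjusted p = 0.784 with estimated correlation for both). Mitochondrial ribosomal proteins had 42 of 69 higher and none lower (46 and 0 over the list alone). The median was 0.50 (camera adjusted p = 4.37e-09), and ergosterol synthesis had 17 of 28 lower and 2 higher (19 and 3 over the list alone, median −0.49; camera adjusted p = 2.92e-05, adjusted p = 0.784 with estimated correlation for both), and ERG2 fell by 1.47 and NCP1 by 1.55. Iron regulon footprints were lower in 12 of 29 and higher in 4 (14 and 4 over the list alone), with the permease FTR1 (−1.51) and the reductase FRE4 (−2.83) down and the iron-sulfur scaffold ISU1 up (0.91). The median was −0.48 (camera adjusted p = 0.0219, adjusted p = 0.784 with estimated correlation). Cytosolic ribosomal proteins were not called as a group in footprints, where 12 of 137 rose and 16 fell (median −0.07, camera adjusted p = 0.505).

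Cell wall and cell surface genes had 23 of 49 members with more footprints in KO and 12 with fewer (25 and 12 over the list alone, median 0.41), the risers including SPI1 (2.15), SED1 (2.09) and TIR3 (3.94). Their camera adjusted p = 0.0219 became 0.111 with the replicate block, 0.0748 without WT footprint replicate 1, and an adjusted p = 0.784 with estimated correlation. Mating and pheromone genes had 15 of 35 higher and 6 lower (18 and 6 over the list alone, median 0.49), with the agglutinin subunit AGA2 (1.89) and the G protein subunit STE18 (1.47) higher. The list had a camera adjusted p = 0.0324, which was 0.0641 with the replicate block, 0.0984 without WT footprint replicate 1, 0.086 without KO footprint replicate 2, and an adjusted p = 0.784 with estimated correlation. Hexose transport and galactose use had 8 of 29 higher and 2 lower (8 and 1 over the list alone), with the glucose sensing regulator MTH1 (3.12) and the transporter HXT5 (3.63) among the risers. The median was 0.56 (camera adjusted p = 0.0282, and 0.0834 with the replicate block, adjusted p = 0.784 with estimated correlation).

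Translational efficiency, the footprint to mRNA ratio, had more rises than falls called in KO, with the median of all genes at −0.064. Whether WT mRNA reads without matching footprints added to the rises was not tested. TIR2 rose by 7.29 on the log2 scale (SE 0.61, n = 2 libraries of each kind per group, edgeR adjusted p = 7.40e-05), and the stress protein DDR2 rose by 4.05 (SE 0.48). SCS3, involved in lipid droplet formation, fell by 2.18 (SE 0.33), and HSP30, whose mRNA had risen, fell by 2.06 (SE 0.37, edgeR adjusted p = 0.00896). Of 5871 genes, 247 rose and 53 fell (94 with the replicate block), 193 and 33 of them by at least 2-fold. Rises made up a smaller share of calls without WT mRNA replicate 1 or KO mRNA replicate 1. That share was larger without any other WT or KO library, and each of these fits called fewer genes.

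Cytosolic ribosomal protein genes, whose mRNA fell and whose footprints were not called as a group, were called upward in translational efficiency, with 46 of 137 higher and none lower (94 and 0 over the list alone, median 0.69, camera adjusted p = 1.01e-34, adjusted p = 0.232 with estimated correlation). Translation factors had 8 of 38 higher and none lower (17 and 0 over the list alone, median 0.55, camera adjusted p = 4.10e-09), and glycolysis and fermentation 4 of 20 higher and none lower (6 and 0 over the list alone, median 0.55, camera adjusted p = 1.58e-07). Both had an adjusted p = 0.232 with estimated correlation. Respiratory chain genes had 14 of 39 higher and none lower (24 and 1 over the list alone, median 0.99, camera adjusted p = 6.42e-14), and the stress response list 13 of 51 higher and 1 lower (22 and 2 over the list alone, median 0.67, camera adjusted p = 4.10e-09). These 2 lists had an adjusted p = 0.232 with estimated correlation as well. Histones had 5 of 11 higher and none lower (7 and 0 over the list alone, median 0.92, camera adjusted p = 2.55e-06), and the TCA and glyoxylate cycle 5 of 27 higher and none lower (median 0.45, camera adjusted p = 4.63e-05), again with an adjusted p = 0.232 with estimated correlation for both. Amino acid biosynthesis had 7 of 66 higher and none lower (median 0.18, camera adjusted p = 0.00058), purine and one-carbon genes 3 of 20 higher and none lower (median 0.30, camera adjusted p = 0.000171), and hexose transport and galactose use 7 of 28 higher and 1 lower (median 0.72, camera adjusted p = 0.00017). All 3 had an adjusted p = 0.232 with estimated correlation. The hexose list holds galactose genes whose WT mRNA had no footprints to match: KO over WT was 0.137 for GAL2 and 0.203 for GAL7 in mRNA, and 1.42 and 1.58 in footprints. Without 5 galactose genes its median was 0.17.

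The cell wall list was called upward in translational efficiency, with 8 of 52 members higher and 3 lower (16 and 6 over the list alone). Its median of 0.17 turned negative on log2(RPKM + 1), where that of all genes was −0.23, and lay 0.14 above that (camera adjusted p = 0.000301, adjusted p = 0.379 with estimated correlation). The iron regulon was the list called downward, although 1 member rose and none fell. Its median was −0.47, also −0.47 with its member at 0 counts in a group set to its bound (camera adjusted p = 0.0401, adjusted p = 0.661 with estimated correlation). That call was lost without WT mRNA replicate 1 (0.0789), KO mRNA replicate 1 (0.186), WT footprint replicate 2 (0.133) or KO footprint replicate 2 (0.0912).

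Across the 5594 genes tested in both kinds of library, mRNA and footprint changes in KO were related (Pearson r 0.50, Spearman rho 0.509, across genes, which are not independent replicates). Both measures rose in 371 genes (114 if the calls were independent) and both fell in 222 (94.5 if independent). In 41 genes mRNA fell while footprints rose, and in 5 the reverse held.

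**Figure D2:**
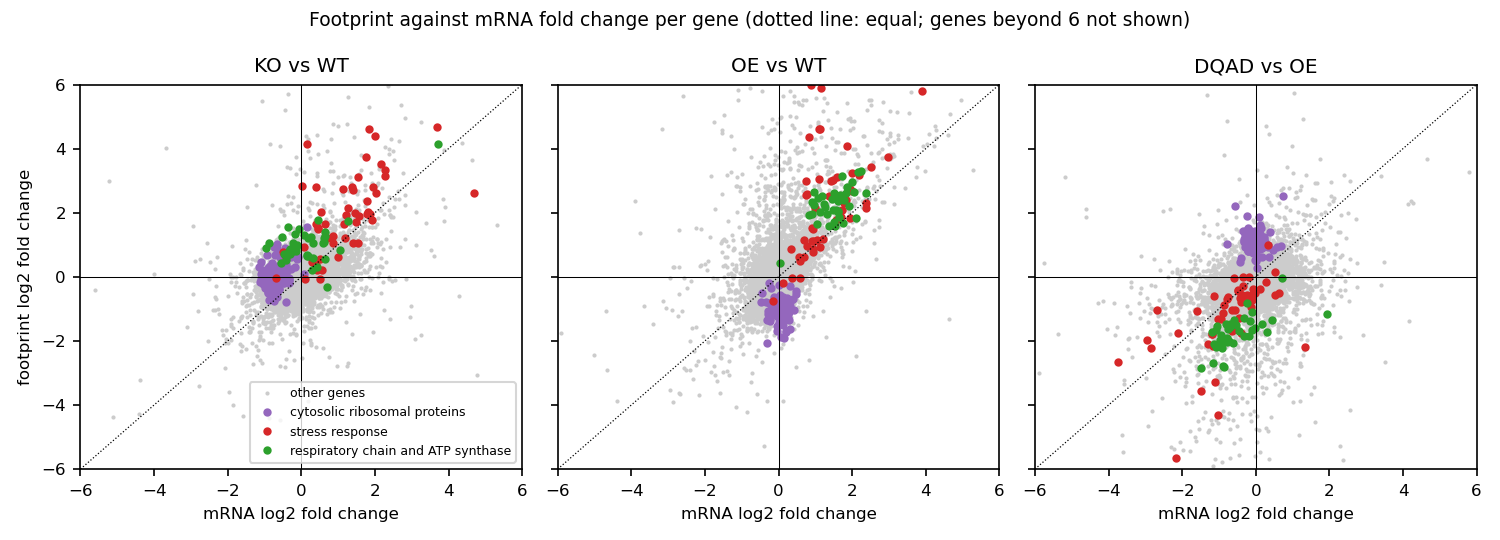
Log2 fold change of mRNA (horizontal axis) and of footprints (vertical axis) per gene for KO against WT, OE against WT and DQAD against OE, with cytosolic ribosomal proteins in purple, stress response genes in red, respiratory genes in green and a dotted line where both are equal; genes beyond 6 on either axis are left out. Ribosomal proteins have medians of −0.73 in mRNA and −0.07 in footprints in KO, and of 0.07 and −1.02 in OE. In DQAD against OE they are −0.07 (0.11 on log2(RPKM + 1), with all genes at 0.13) and 1.09.

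OE against WT measures Dhh1 excess together with the plasmid and the dropout medium. In mRNA, OPT2, an oligopeptide transporter, rose by 4.26 on the log2 scale (SE 0.27, n = 2 per group, edgeR adjusted p = 9.98e-08), the transaldolase NQM1 by 4.24 (SE 0.38) and GAL10 of galactose use by 4.48 (SE 0.38, uncertain because of an overlapping noncoding RNA). PHM6, a phosphate-regulated gene, fell by 5.02 (SE 0.68), and of the iron uptake genes FRE1 fell by 2.71 (SE 0.31) and ENB1 fell by 2.57 (SE 0.30). Of 5715 genes, 373 rose and 226 fell (376 with the replicate block), 287 and 106 of them by at least 2-fold; the total of 599 became 399 without OE mRNA replicate 1. Rises made up 62.3% of the calls, against 81.1% on log2(RPKM + 1).

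The respiratory chain and ATP synthase rose as a group in OE mRNA: 37 of 39 members rose and none fell (38 and 0 over the list alone), such as the NADH dehydrogenase NDI1 (2.37, SE 0.19), QCR6 (2.00) and COX6 (1.92). The median was 1.53 (camera adjusted p = 1.23e-46, adjusted p = 0.123 with estimated correlation). The TCA and glyoxylate cycle had 14 of 26 higher and 2 lower (17 and 2 over the list alone), with KGD2 (1.89) and LSC2 (1.58) among the risers. The median was 0.94 (camera adjusted p = 4.74e-11, adjusted p = 0.194 with estimated correlation). In the stress response list 32 of 51 rose and none fell (42 and 0 over the list alone), including the glycogen enzymes GPH1 (2.97) and GLC3 (2.50). The median was 1.13 (camera adjusted p = 1.90e-33, adjusted p = 0.125 with estimated correlation). Nitrogen catabolite genes had 18 of 40 higher and 3 lower (22 and 7 over the list alone), with proline oxidase PUT1 (3.02) and arginase CAR1 (2.03) higher (median 0.88, camera adjusted p = 1.67e-11, adjusted p = 0.169 with estimated correlation). Hexose transport and galactose use had 10 of 28 higher and 5 lower (13 and 6 over the list alone), with GAL3 among the risers (3.35) and a median of 1.01, or 0.66 without 5 galactose genes and 0.88 with members at 0 counts in a group set to their bounds (camera adjusted p = 7.69e-05, adjusted p = 0.249 with estimated correlation).

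Phosphate genes had 11 of 24 lower in OE mRNA and none higher (13 and 0 over the list alone), among them the transporter PHO89 (−1.45) and VTC3 of polyphosphate synthesis (−1.72). The median was −0.92 (camera adjusted p = 1.07e-12, adjusted p = 0.123 with estimated correlation). The iron regulon had 12 of 29 lower and 1 higher (17 and 1 over the list alone, median −0.82, camera adjusted p = 2.51e-09, adjusted p = 0.136 with estimated correlation). Ribosome biogenesis had 22 of 105 lower and none higher (31 and 0 over the list alone, median −0.47), with a camera adjusted p = 3.03e-11 and an adjusted p = 0.194 with estimated correlation. Cytosolic ribosomal protein mRNA showed no call in any of 137 members. The median was 0.07 (camera adjusted p = 0.767); camera called the list downward without OE mRNA replicate 1 (0.0139) and upward without replicate 2 (0.0111). Purine and one-carbon genes had 6 of 20 lower and none higher (median −0.46, camera adjusted p = 6.87e-06, adjusted p = 0.125 with estimated correlation). Ergosterol synthesis had 4 of 28 lower and none higher (median −0.34, camera adjusted p = 0.00185, adjusted p = 0.194 with estimated correlation). Mitochondrial ribosomal proteins had 3 of 69 higher and none lower (median 0.39, camera adjusted p = 0.00185, adjusted p = 0.238 with estimated correlation).

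Calls of 3 further lists in OE mRNA each hung on 1 library or more. Glycolysis and fermentation had 4 of 20 higher and none lower (median 0.23, camera adjusted p = 0.0329, adjusted p = 0.661 with estimated correlation), and the call was lost without WT mRNA replicate 1 (0.0703) or OE mRNA replicate 1 (0.303). Mating genes had 7 of 34 lower and 1 higher, with the agglutinin subunit AGA1 down (−1.60) and the cell cycle arrest gene FAR1 up (1.26). The median was −0.28 (camera adjusted p = 0.0137, adjusted p = 0.277 with estimated correlation), and without WT mRNA replicate 1 the camera adjusted p was 0.0509. Meiosis and sporulation had 4 of 47 higher and none lower (1 and 0 over the list alone), with the RNA-binding protein RIM4 up by 3.23 (SE 0.30). The median was 0.76 (camera adjusted p = 0.00585, adjusted p = 0.383 with estimated correlation), and without OE mRNA replicate 1 the camera adjusted p was 0.0512.

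Footprints moved more widely than mRNA in OE. Sporulation genes that had almost no footprints in WT gained them, with OE mRNA under 1 CPM: SPO77 rose by 11.32 on the log2 scale (SE 0.26, n = 2 per group, edgeR adjusted p = 2.55e-06). SPO19 and MER1, at 0 counts in WT, were at least 2700-fold and at least 1440-fold higher. RNP1, an RNA-binding protein, had 22079 counts in OE and 2 in WT, a ratio of 4920 (counting interval 1360 to 40700), and GAL7 of galactose use rose by 9.09 (SE 0.38). FIT1 fell by 6.71 (SE 0.79), ANB1, the hypoxic form of eIF5A, fell by 4.22, and of the glucose transporters HXT2 fell by 4.06 and HXT4 fell by 3.65. Of 5789 genes, 1770 rose and 1554 fell, 1014 and 379 of them by at least 2-fold. Rises made up 53.2% of the calls, against 82.2% on log2(RPKM + 1), where the median of all genes lay at 0.48.

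The translation machinery lost footprints in OE. Among cytosolic ribosomal proteins 133 of 137 fell and none rose (0 up and 135 down over the list alone, median −1.02, camera adjusted p = 5.19e-24), and ribosome biogenesis had 97 of 105 lower and 3 higher (98 and 3 over the list alone). The median was −0.89 (camera adjusted p = 5.06e-20, adjusted p = 0.241 with estimated correlation for both). All 38 translation factors fell (38 over the list alone, median −0.86), among them the elongation factor subunits TEF4 (−1.69) and EFB1 (−1.60), both uncertain because snoRNA genes lie within them (camera adjusted p = 1.26e-08, adjusted p = 0.362 with estimated correlation). Glycolysis and fermentation had 13 of 20 lower and 3 higher (14 and 4 over the list alone), with pyruvate kinase CDC19 down (−1.71, SE 0.10) and hexokinase HXK1 (3.65) and the minor pyruvate decarboxylase PDC6 (5.57) up. The median was −1.04 (camera adjusted p = 0.00224, adjusted p = 0.241 with estimated correlation).

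Respiratory chain footprints rose in 38 of 39 members of the list and fell in none (39 and 0 over the list alone), with the succinate dehydrogenase subunits SDH2 (3.30) and SDH1 (3.27) among them. The median was 2.28 (camera adjusted p = 5.19e-24), and the stress response list had 46 of 51 higher and 1 lower (47 and 1 over the list alone), such as DDR2 (5.89) and the Hsp70 SSA3 (5.98). The median was 2.30 (camera adjusted p = 1.21e-25, adjusted p = 0.241 with estimated correlation for both). The TCA and glyoxylate cycle had 24 of 27 higher and 1 lower, with citrate synthase CIT1 (2.51) and PCK1 of gluconeogenesis (3.66) up. The median was 1.17 (camera adjusted p = 4.07e-06), and nitrogen catabolite genes had 28 of 40 higher and 8 lower, with the permeases MEP2 (5.45) and GAP1 (4.89) up. The median was 1.15 (camera adjusted p = 5.61e-07, adjusted p = 0.241 with estimated correlation for both). Meiosis and sporulation had 39 of 58 higher and none lower (39 and 0 over the list alone), the recombinase DMC1 among them (5.16). The median was 2.81, also 2.81 with its 3 members at 0 counts in a group set to their bounds (camera adjusted p = 3.07e-06, adjusted p = 0.241 with estimated correlation). Hexose transport and galactose use had 16 of 29 higher and 3 lower (median 2.25, or 0.89 without 5 galactose genes, camera adjusted p = 1.47e-05), and autophagy genes had 22 of 39 higher and 2 lower, with ATG14 (5.46) and ATG8 (1.74) up (median 0.81, camera adjusted p = 0.00739, adjusted p = 0.241 with estimated correlation for both). Mitochondrial ribosomal proteins had 62 of 69 higher and none lower (median 0.62, camera adjusted p = 2.59e-06, adjusted p = 0.573 with estimated correlation).

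Phosphate genes again fell in OE footprints, 19 of 24 with 2 higher, including PHO84 (−3.63, uncertain because of an overlapping noncoding RNA), VTC3 (−3.05) and VTC4 (−2.24). The median was −1.55 (camera adjusted p = 7.87e-11, adjusted p = 0.241 with estimated correlation). The iron regulon had 17 of 29 lower and 2 higher (median −1.11, camera adjusted p = 0.000556, adjusted p = 0.363 with estimated correlation). Purine and one-carbon genes had 15 of 20 lower and 1 higher (median −0.85, camera adjusted p = 6.41e-05), and ergosterol synthesis 24 of 28 lower and 2 higher (median −0.78, camera adjusted p = 4.74e-06); both had an adjusted p = 0.241 with estimated correlation. Proteasome genes had 18 of 35 lower and 2 higher, RPT2 (1.21) and the transcription factor RPN4 (0.63). Their median of −0.31 turned positive on log2(RPKM + 1), −0.33 relative to all genes (camera adjusted p = 0.0171, adjusted p = 0.721 with estimated correlation).

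In the translational efficiency of OE against WT, FKS3, a spore wall synthesis gene, rose by 8.02 on the log2 scale (SE 0.45, n = 2 libraries of each kind per group, edgeR adjusted p = 5.42e-07), and AIM26, with a group at 0 counts, was at least 726-fold higher. FIT1 fell by 6.08 (SE 0.91), HXT4 fell by 3.02 and HXT2 fell by 2.87. Of 5871 genes, 469 rose and 306 fell, 426 and 159 of them by at least 2-fold; the total of 775 became 431 without WT footprint replicate 2. Rises made up 60.5% of the calls, against 83.0% on log2(RPKM + 1), where the median of all genes lay at 0.38.

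Of the cytosolic ribosomal proteins 109 of 137 fell in translational efficiency and none rose (0 up and 128 down over the list alone, median −1.05, camera adjusted p = 1.92e-52, adjusted p = 0.321 with estimated correlation), as did 20 of 38 translation factors with none higher (26 and 0 over the list alone). Translation factors had a median of −0.81 (camera adjusted p = 1.91e-12), and glycolysis and fermentation had 12 of 20 lower and 2 higher (median −1.09, camera adjusted p = 1.48e-09, adjusted p = 0.321 with estimated correlation for both), and ergosterol synthesis 5 of 28 lower and 1 higher. The ergosterol median was −0.53 (camera adjusted p = 0.000392, adjusted p = 0.321 with estimated correlation). Ribosome biogenesis had 17 of 105 lower and 2 higher (median −0.39, camera adjusted p = 2.21e-07, adjusted p = 0.348 with estimated correlation), and the stress response list 19 of 51 higher and none lower (median 0.58, camera adjusted p = 1.69e-07, adjusted p = 0.348 with estimated correlation). The respiratory chain had 12 of 39 higher and none lower (21 and 0 over the list alone, median 0.90, camera adjusted p = 3.03e-06, adjusted p = 0.45 with estimated correlation), and hexose transport and galactose use 15 of 28 higher and 2 lower (median 1.63, camera adjusted p = 7.93e-05, adjusted p = 0.333 with estimated correlation). Without 5 galactose genes, whose WT mRNA had few footprints, 10 of 23 were higher and 2 lower, with a median of 0.18. With the replicate block 19 of the 24 lists were called, against 11 without it.

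Further calls in the translational efficiency of OE depended on the library set. Phosphate genes had 7 of 24 lower and 1 higher. The median of −0.36 turned positive on log2(RPKM + 1), −0.31 relative to all genes. The camera adjusted p = 0.00348 became 0.063 without OE footprint replicate 1, and the list had an adjusted p = 0.428 with estimated correlation. Purine and one-carbon genes had 2 of 20 lower and 1 higher, with a median of −0.33 that also turned positive, −0.32 relative to all genes. Their camera adjusted p = 0.0167 became 0.0501 without OE mRNA replicate 2 and 0.0819 without OE footprint replicate 1, and was an adjusted p = 0.333 with estimated correlation. Meiosis and sporulation had 11 of 58 higher and none lower (13 and 0 over the list alone). The median was 1.23, or 1.68 with its 8 members at 0 counts in a group set to their bounds. Here the camera adjusted p = 0.00934 became 0.28 without WT mRNA replicate 1, and there was an adjusted p = 0.45 with estimated correlation. Across 5594 genes, mRNA and footprint changes in OE had a Pearson r of 0.545 (Spearman rho 0.517). Both rose in 350 genes (111 if independent) and both fell in 170 (61.8 if independent), and in 12 genes mRNA fell while footprints rose.

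**Figure D3:**
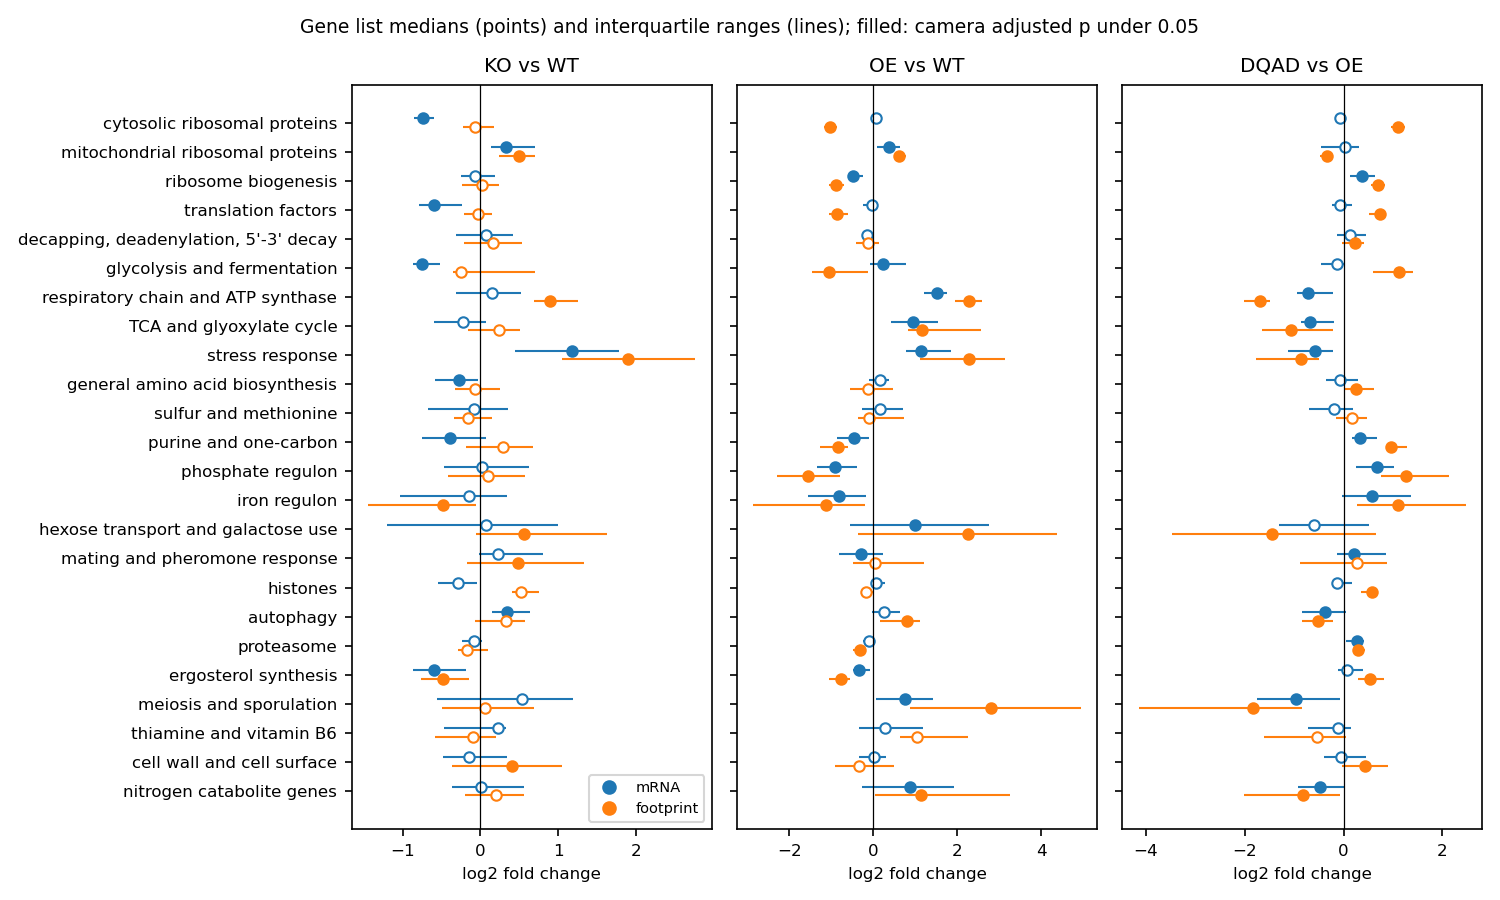
Median log2 fold change of each of the 24 gene lists (points) with the interquartile range over its members (lines) for KO against WT, OE against WT and DQAD against OE, mRNA in blue and footprints in orange; filled points have a camera adjusted p under 0.05. Of the filled footprint medians, those of the proteasome in OE against WT and of mRNA decay factors, amino acid biosynthesis, the proteasome and the cell wall in DQAD against OE turned sign under scaling to library totals, as did 50 of 216 list medians in all (translational efficiency included), 15 of them of called lists; relative to the median of all genes, none of the called lists turned.

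DQAD against OE asks which changes need the catalytic activity of Dhh1. The labels give both the same plasmid type and medium, but galactose gene footprints differed (GAL7 at a mean of 3957 CPM in OE and 3.73 CPM in DQAD), so the same sugar state cannot be assumed. With 1 DQAD library per kind, the test has no replicate on that side. It shares the OE libraries with OE against WT, so reversed signs are not independent evidence. In mRNA, GCV1 of glycine breakdown rose by 2.51 on the log2 scale (SE 0.24, n = 1 against 2, edgeR adjusted p = 9.34e-05) and the iron reductase FRE1 by 2.40 (SE 0.34). ALD3, a stress-induced aldehyde dehydrogenase, fell by 3.73 (SE 0.73, edgeR adjusted p = 0.0112), XBP1, a stress-induced repressor, fell by 2.69 and CYB2, a lactate dehydrogenase, fell by 2.48. Of 5715 genes, 154 rose and 82 fell, 126 and 71 of them by at least 2-fold. The total of 236 became 717 (448 up, 269 down) with the replicate block. Numbered replicate 1 but named like replicate 2, the DQAD mRNA library has an uncertain place in that block. On log2(RPKM + 1), with 35 calls, FRE1, ALD3 and CYB2 were not called. Rises made up 65.3% of the calls, against 53.2% with DESeq2.

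Ribosome biogenesis had 11 of 105 members higher in DQAD mRNA and none lower (24 and 0 over the list alone). The median was 0.37 (camera adjusted p = 5.97e-09, adjusted p = 0.346 with estimated correlation). Phosphate genes had 8 of 24 higher and none lower (13 and 0 over the list alone), including PHM6 (4.13) and VTC3 (1.20). The median was 0.67 (camera adjusted p = 1.75e-08, adjusted p = 0.296 with estimated correlation). Purine and one-carbon genes had 3 of 20 higher and none lower (median 0.33, camera adjusted p = 3.41e-05, adjusted p = 0.296 with estimated correlation). The iron regulon had 6 of 29 higher and none lower (10 and 0 over the list alone), with the siderophore transporters ENB1 (2.12) and SIT1 (1.11) among them. The median was 0.57 (camera adjusted p = 1.59e-05, adjusted p = 0.346 with estimated correlation). The stress response list was called downward, with 11 of 51 lower and none higher (16 and 0 over the list alone, median −0.57, camera adjusted p = 8.14e-09), and respiratory chain mRNAs fell in 6 of 39 members, QCR6 among them (−1.48), and rose in 1 (19 and 1 over the list alone, median −0.72, camera adjusted p = 5.83e-08, adjusted p = 0.346 with estimated correlation for both). The TCA and glyoxylate cycle had 3 of 26 lower, PYC1 among them (−1.05), and 2 higher, DLD3 (1.46) and CIT2 (1.24), both targets of the mitochondrial retrograde pathway. The median was −0.69 (camera adjusted p = 0.000163, adjusted p = 0.489 with estimated correlation). Ribosomal protein mRNA showed no call (camera adjusted p = 0.492). Its median of −0.07 turned positive on log2(RPKM + 1), with all genes at 0.13. Camera called the list upward without OE mRNA replicate 1 and downward without replicate 2. On log2(RPKM + 1), VTC3, ENB1, SIT1, QCR6, PYC1, DLD3 and CIT2 were not called.

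Mating genes had 3 of 34 higher in DQAD mRNA and none lower, with the agglutinin subunit AGA1 (1.60) and the pheromone protease BAR1 (1.13) among them. The median was 0.21 (camera adjusted p = 0.0123, adjusted p = 0.418 with estimated correlation). Nitrogen catabolite genes had 4 of 40 lower and 1 higher (10 and 4 over the list alone), with OPT2 (−1.56) among the lower ones. The median was −0.48 (camera adjusted p = 0.00277, adjusted p = 0.519 with estimated correlation). AGA1, BAR1 and OPT2 were not called on log2(RPKM + 1). Meiosis and sporulation had 1 of 47 lower and none higher. The median was −0.97, also −0.97 with its 3 members at 0 counts in a group set to their bounds (camera adjusted p = 0.00159, adjusted p = 0.489 with estimated correlation). The proteasome list was called upward with 1 of 35 higher (median 0.28, camera adjusted p = 0.00693, and 0.0888 without OE mRNA replicate 1), with an adjusted p = 0.567 with estimated correlation. Autophagy was called downward with no member past the threshold. The median was −0.37 (camera adjusted p = 0.0358, and 0.0524 without OE mRNA replicate 2), with an adjusted p = 0.346 with estimated correlation.

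Footprints differed more widely between DQAD and OE. Some genes that gained footprints in OE were far lower in DQAD: GAL7 fell by 10.05 on the log2 scale (SE 0.56, n = 1 against 2), SPO19 was at least 751-fold lower, and SPO77, with 3 counts in DQAD, was lower by a ratio of 1030 (counting interval 354 to 5010). HXT4 rose by 4.45 (SE 0.25), HXT2 by 4.09 and ANB1 by 4.93. Of 5789 genes, 1067 rose and 1153 fell, 281 and 724 of them by at least 2-fold; over the compared groups only, 593 rose and 716 fell. Rises made up 48.1% of the calls, against 12.8% on log2(RPKM + 1), where the median of all genes lay at −0.48.

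Cytosolic ribosomal proteins had 133 of 137 members with more footprints in DQAD than in OE and none with fewer (134 and 0 over the list alone, median 1.09, camera adjusted p = 1.15e-38, adjusted p = 0.267 with estimated correlation). Ribosome biogenesis had 90 of 105 higher and 2 lower (93 and 3 over the list alone). The median was 0.69 (camera adjusted p = 2.32e-17, adjusted p = 0.207 with estimated correlation). Translation factors had 32 of 38 higher and none lower (35 and 0 over the list alone, median 0.73, camera adjusted p = 1.34e-08, adjusted p = 0.339 with estimated correlation). Glycolysis and fermentation had 14 of 20 higher and 3 lower (median 1.13, camera adjusted p = 5.84e-06), and phosphate genes had 19 of 24 higher and 1 lower, with VTC3 (2.72) and VTC4 (2.08) up. The median was 1.26 (camera adjusted p = 6.69e-14, adjusted p = 0.207 with estimated correlation for both). Purine and one-carbon genes had 17 of 20 higher and 1 lower (median 0.96, camera adjusted p = 6.22e-07, adjusted p = 0.207 with estimated correlation). The iron regulon had 14 of 29 higher and none lower, with FRE4 (3.17) and FTR1 (1.25) up. The median was 1.11 (camera adjusted p = 3.53e-05), and ergosterol synthesis had 17 of 28 higher and 2 lower (median 0.54, camera adjusted p = 8.35e-05, adjusted p = 0.294 with estimated correlation for both). Histones had 6 of 11 higher and none lower (7 and 0 over the list alone, median 0.58, camera adjusted p = 0.0247, adjusted p = 0.434 with estimated correlation).

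Respiratory chain genes had 38 of 39 members with fewer footprints in DQAD and none with more, with SDH1 (−2.82), SDH2 (−2.68) and QCR6 (−2.85) among them. The median was −1.68 (camera adjusted p = 8.29e-20), and the stress response list had 40 of 51 lower and 1 higher (43 and 1 over the list alone), with SSA3 at −4.30. The median was −0.87 (camera adjusted p = 6.80e-10, adjusted p = 0.294 with estimated correlation for both). The TCA and glyoxylate cycle had 18 of 27 lower and none higher. The median was −1.07 (camera adjusted p = 0.000387, adjusted p = 0.267 with estimated correlation). Nitrogen catabolite genes had 20 of 40 lower and 5 higher, with PUT4 (−4.61) and OPT2 (−4.50) lower (median −0.81, camera adjusted p = 0.00035), and autophagy genes had 10 of 39 lower and 1 higher (median −0.51, camera adjusted p = 0.0136, adjusted p = 0.294 with estimated correlation for both). Meiosis and sporulation had 25 of 58 lower and none higher (27 and 0 over the list alone). The median was −1.83, or −1.71 with its 5 members at 0 counts in a group set to their bounds (camera adjusted p = 4.50e-06, adjusted p = 0.207 with estimated correlation). Hexose transport and galactose use had 15 of 29 lower and 3 higher. The median was −1.46, or −0.41 without 5 galactose genes, and the camera adjusted p = 3.93e-05 became 0.0692 without OE footprint replicate 1 and 0.0578 without OE footprint replicate 2. That list had an adjusted p = 0.207 with estimated correlation. Mitochondrial ribosomal proteins had 22 of 69 lower and none higher. The median was −0.34 (camera adjusted p = 0.00165, adjusted p = 0.599 with estimated correlation).

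Some upward calls in DQAD footprints had medians that turned sign on log2(RPKM + 1) and stayed positive relative to all genes there. That scale did not move all genes alike. Of the mRNA decay factors, 13 of 36 were higher and 1 lower, with the decapping activators EDC1 (1.02) and PAT1 (0.99) higher. Their median of 0.23 turned negative, 0.24 relative to all genes (camera adjusted p = 0.0213, adjusted p = 0.393 with estimated correlation). Amino acid biosynthesis had 24 of 66 higher and 6 lower, with BAT2 of branched-chain synthesis higher (1.61). Its median of 0.25 turned negative, 0.28 relative to all genes (camera adjusted p = 0.00418, adjusted p = 0.294 with estimated correlation). The proteasome had 11 of 35 higher and 1 lower, with a median of 0.29 that turned negative, 0.31 relative to all genes (camera adjusted p = 0.0121, adjusted p = 0.588 with estimated correlation). In the cell wall list 21 of 49 were higher and 3 lower, with SUN4 (1.49) and TIR1 (2.94) higher and NCA3 (−1.61) lower. Its median of 0.43, or 0.45 with bounds for members at 0 counts in a group, turned negative as well, 0.46 relative to all genes (camera adjusted p = 0.00162, adjusted p = 0.428 with estimated correlation).

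In the translational efficiency of DQAD against OE, HXT4 rose by 4.03 on the log2 scale (SE 0.44, n = 1 against 2 libraries of each kind), and HXT2 by 3.07, the latter not called over the compared groups alone. GAL7 fell by 8.58 and GAL1 fell by 8.33 (GAL1 uncertain because of an overlapping noncoding RNA). SPO77, with 3 mRNA counts in OE and 3 footprint counts in DQAD, was lower by a ratio of 5970 (counting interval 699 to 140000). Of 5871 genes, 204 rose and 394 fell, 174 and 374 of them by at least 2-fold; over the compared groups only, 28 rose and 214 fell. Rises made up 34.1% of the calls, against 6.7% on log2(RPKM + 1), where the median of all genes lay at −0.60, and 45.9% with DESeq2.

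The ribosomal protein list was called upward in the translational efficiency of DQAD, with 94 of 137 higher and none lower (127 and 0 over the list alone, median 1.14, camera adjusted p = 1.84e-47, adjusted p = 0.299 with estimated correlation). Translation factors had 11 of 38 higher and none lower (15 and 0 over the list alone, median 0.62, or 0.03 on log2(RPKM + 1) and 0.63 relative to all genes, camera adjusted p = 2.78e-09). Glycolysis and fermentation had 10 of 20 higher and 1 lower (16 and 1 over the list alone, median 1.17, camera adjusted p = 7.47e-09). Both had an adjusted p = 0.299 with estimated correlation. The respiratory chain had 17 of 39 lower and none higher (28 and 0 over the list alone, median −1.16, camera adjusted p = 1.61e-12), and hexose transport and galactose use 12 of 28 lower and 2 higher (15 and 2 over the list alone, median −2.09, camera adjusted p = 7.37e-06). These 2 lists also had an adjusted p = 0.299 with estimated correlation. Without 5 galactose genes, 7 of 23 in the hexose list were lower and 2 higher, with a median of −0.09. Amino acid biosynthesis (3 higher, none lower; median 0.26, camera adjusted p = 0.0028), purine and one-carbon (2 higher, 1 lower; median 0.59, camera adjusted p = 0.00577) and ergosterol synthesis (2 higher, none lower; median 0.44, camera adjusted p = 0.0028) were called upward, all 3 with an adjusted p = 0.299 with estimated correlation. Their medians turned negative on log2(RPKM + 1) and were 0.28, 0.59 and 0.44 relative to all genes. The phosphate median turned negative too (6 higher, none lower; 0.44, 0.36 relative to all genes, camera adjusted p = 0.0028, adjusted p = 0.41 with estimated correlation).

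Other list calls in the translational efficiency of DQAD were lost in some fits. Mitochondrial ribosomal proteins had 1 member higher and 7 lower (median −0.46, camera adjusted p = 0.0469, adjusted p = 0.626 with estimated correlation). They were not called with RLE size factors (0.0625), without OE mRNA replicate 1 (0.0882) or without OE footprint replicate 1 (0.244). The stress response list had 1 higher and 6 lower (median −0.42, camera adjusted p = 0.022, adjusted p = 0.612 with estimated correlation). It was not called with the replicate block (0.183), without OE mRNA replicate 2 (0.165) or without OE footprint replicate 1 (0.101). The iron regulon had 3 higher and 2 lower, with a median of 0.27, or 0.46 with bounds for members at 0 counts in a group (camera adjusted p = 0.0163, adjusted p = 0.532 with estimated correlation). Its call was lost without OE mRNA replicate 2 (0.0912) or OE footprint replicate 1 (0.0831). Ribosome biogenesis had 5 higher and 3 lower, with a median of 0.26 that turned negative on log2(RPKM + 1), 0.27 relative to all genes. The camera adjusted p = 0.00371 became 0.0965 without OE mRNA replicate 2, with an adjusted p = 0.532 with estimated correlation. Sulfur and methionine genes had 3 of 32 higher and none lower, with a median of 0.24 that turned negative, 0.29 relative to all genes. The camera adjusted p = 0.0218 became 0.0521 without OE mRNA replicate 1, with an adjusted p = 0.32 with estimated correlation. The cell wall list had 1 higher and 1 lower, and its median of 0.30 turned negative, 0.35 relative to all genes. The camera adjusted p = 0.013 became 0.0514 without OE mRNA replicate 1, with an adjusted p = 0.532 with estimated correlation. Thiamine and vitamin B6 genes were called in none of the 9 comparisons (camera adjusted p = 0.216 to 0.803), but without OE footprint replicate 1 in footprints of OE (0.0146) and DQAD (0.0404). Across 5594 genes, mRNA and footprint differences between DQAD and OE had a Pearson r of 0.343 (Spearman rho 0.35). Both rose in 72 genes (28.3 if independent), both fell in 72 (15.9 if independent), and in 11 mRNA rose while footprints fell.

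Loss of Dhh1 can be set beside excess of inactive in place of active Dhh1 across genes, since KO against WT and DQAD against OE share no library. The difference in galactose gene footprints between OE and DQAD enters these values, and its part was not separated. Over all genes tested the changes in mRNA and footprints were weakly opposed: Pearson r was −0.204 in mRNA (Spearman rho −0.129), −0.214 in footprints (−0.239) and −0.087 in translational efficiency (−0.027; library pairs −0.123 to 0.029), across genes, which are not independent replicates. Over genes with at least 100 counts in every library, the values were −0.007 in mRNA and 0.124 in translational efficiency. In footprints, 439 genes rose in KO and fell in DQAD (242 if independent) and 310 fell in KO and rose in DQAD (184 if independent), while 147 rose in both (224 if independent) and 108 fell in both (198 if independent). In mRNA, 40 rose in KO and fell in DQAD (7.63), 13 fell in KO and rose in DQAD (14.2), 20 rose in both (14.1) and 5 fell in both (7.67). In translational efficiency, 39 rose in both (8.56 if independent) and 37 rose in KO and fell in DQAD (16.5 if independent). KO and OE, both set against the same WT libraries, had a Pearson r of 0.444 in mRNA, where unchanged groups simulated against those libraries gave 0.516, and a covariance of 0.314 against 0.0764 simulated. In footprints r was 0.398 against 0.57 simulated, and the covariance was 0.648 against 0.0602 simulated. Both comparisons called 151 genes up in mRNA (34.7 if independent; 0 simulated, where unchanged groups give almost no calls), and 728 up (371.5 if independent) and 554 down (267.4 if independent) in footprints; part of the excess may come from the shared controls, since 2 WT libraries cannot be split into pairs. With KO set against 1 WT library and OE against the other, both ways round, r was 0.241 and 0.28 in mRNA (covariance 0.221 and 0.249) and 0.36 and 0.331 in footprints (0.694 and 0.596). Both then rose in 129 and 127 genes in mRNA (35.5 and 32.7 if independent) and in 451 and 440 in footprints (190 and 173).

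Fold changes were also set against gene properties. With coding length, rho for KO translational efficiency was −0.188 (library pairs −0.217 to −0.096, against up to 0.174 in size for replicate differences), and −0.38 over genes with at least 100 counts. Those pairs reached into the replicate range, where rho with length over all genes lay in the other 8 comparisons. Genes with more mRNA in WT lost more footprints in OE (Spearman rho −0.565, against up to 0.178 in size for replicate differences) and had lower translational efficiency there (−0.412, against 0.212). DQAD against OE, which shares the OE libraries, gave the opposite sign in footprints, 0.523 (against 0.178), and 0.352 (against 0.2) with the WT footprint to mRNA ratio. These are correlations across genes, which are not independent replicates.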

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

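The interaction tests and the comparison of footprint to mRNA ratios with those of other genes in WT were chosen before the results they measure were seen, the other tests in this part only afterwards. In OE, 21 of the 125 genes whose footprints rose by more than 4 on the log2 scale to at least 5 CPM had under 1 CPM of mRNA in both OE libraries, SPO77, SPO19, MER1, AIM26 and RNP1 among them, and 10 of the 21 had a higher footprint to mRNA ratio in OE than in WT, a difference between groups found by the interaction test that the choice of the set favours. Carry-over from another analysed library is argued against, since 0 of the 21 reached their lower OE footprint level in any of the 8 libraries whose level the choice of the set left free, and reads shared with an overlapping gene are argued against, since 0 of the 21 overlap another annotated gene. Translation of scarce mRNAs at ratios found for other genes stays open: the median log2 footprint to mRNA ratio of the set in OE was 6.42, but the way the set was chosen alone puts every ratio above 2.32, past the 1.54 that 0.1% of 5555 genes exceeded in WT, so the comparison decides nothing. Over both OE libraries these genes had at most 8 mRNA counts and at least 950 footprint counts. Footprint and mRNA samples that came from cultures in different states stay open, untested, as does an effect of Dhh1 excess.

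The footprint to mRNA ratio of GAL1 changed by −8.33 on the log2 scale from OE to DQAD, a difference between groups found by the interaction test, because GAL1 mRNA was present in DQAD and its footprints were nearly absent. A DQAD mRNA library partly made of OE mRNA would give every gene at least the admixed share. It is argued against by 14 of 40 other genes high in OE, which lay below 0.5 times the lowest DQAD to OE share among the galactose genes (galactose shares 0.351 to 0.447, median of the others 0.279). A DQAD footprint library from cells without the plasmid is argued against by LEU2 footprints, 605 times higher in DQAD than in WT. Inactive Dhh1 holding galactose mRNAs off ribosomes cannot be told apart from mRNA and footprint samples that differed in sugar response, because the median log2 ratio of 5 galactose genes was low in WT as well (−4.82 in WT, −2.68 in KO, −0.23 in OE and −8.27 in DQAD; WT minus OE −4.58).

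The footprint to mRNA ratio of LEU2 was higher in OE than in WT by 8.45 on the log2 scale, a difference between groups found by the interaction test, because the WT mRNA libraries held LEU2 reads while the WT footprint libraries held almost none. Carry-over of OE mRNA into the WT mRNA libraries is argued against, since the WT to OE shares of LEU2, URA3, GAL1, GAL2, GAL7 and GAL10 ranged over 210-fold, from 0.0447 to 9.38, and over 7.49-fold without URA3. A common source of reads entering both WT mRNA libraries at different shares is consistent with the log2 ratios of WT replicate 1 to replicate 2, which lay within 0.29 of each other over the 6 genes, at a median of 1.48 against 0 for all genes. That source is not given, and neither its entry into KO or DQAD mRNA nor a biological explanation was tested.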

How the results depend on the processing

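Alternatives were planned, except those given above as added after the data were seen. Of 412 results for named genes and 119 called gene list results, the named genes kept direction and call in 411 with RLE size factors (1 newly called), 408 without a count filter (4 newly called), 401 with DESeq2 (1 newly called, 9 lost), 383 over the compared groups only (11 newly called, 13 lost) and 352 on log2(RPKM + 1) (4 newly called, 55 lost, 1 reversed). The reversed one was PRE1 in DQAD against OE footprints, 0.46 and −0.008 on log2(RPKM + 1). Without the DQAD libraries, 258 named results were kept and 1 was newly called, and all 71 list results were kept. In all, 85 named results lost the call under at least 1 alternative, 40 of them on leaving out a library, and 20 list results lost it under an alternative other than an estimated correlation. With that correlation camera called 0 of 24 lists in each of the 9 comparisons, and 24 of 216 had an unadjusted p under 0.05.

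With the replicate block, 398 named results were kept, 11 newly called and 3 lost (ENO2 in KO mRNA, ADH4 and PDC5 in DQAD footprints), and 115 list results were kept, 4 lost and 13 newly called. Genes called in DQAD against OE mRNA numbered 717 with the replicate block against 236, and lists called in OE translational efficiency 19 against 11; falls went from 226 to 376 in OE mRNA and from 53 to 94 in KO translational efficiency. The block moved no other total of calls by over 1.5 times. The mRNA count for DQAD was 724 over the compared groups only and 35 on log2(RPKM + 1). KO translational efficiency had 463 genes over the compared groups only and 469 with DESeq2, against 300. DQAD footprints had 1309 over the compared groups only, against 2220, and DQAD translational efficiency 242 over the compared groups only and 1345 on log2(RPKM + 1), against 598. Fewer libraries estimate the spread in the fits over the compared groups only; for the other changes in this part the cause was not tested.

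Leaving out 1 library at a time, the counts of genes ranged from 239 to 1098 for KO mRNA (1068 in full), 903 to 1448 for KO footprints (2211), 76 to 280 for KO translational efficiency, 399 to 745 for OE mRNA (599), 431 to 893 for OE translational efficiency (775) and 129 to 549 for DQAD mRNA. Where this left 1 library in a group, it was assumed to vary like the other groups. Rank correlations with coding length ranged from −0.018 to 0.043 for KO mRNA, −0.213 to −0.107 for KO footprints and −0.078 to 0.032 for OE mRNA. For DQAD footprints, those with WT mRNA level ranged from 0.45 to 0.546 and with the WT footprint to mRNA ratio from 0.253 to 0.387. The correlation of KO with inactive Dhh1 ranged from −0.258 to −0.163 in footprints and −0.117 to −0.017 in translational efficiency.

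Over genes with at least 100 counts in every library, that correlation was −0.007 in mRNA and 0.124 in translational efficiency, and the relation of OE footprints to WT mRNA level was −0.468. Coding length then gave 0.204 for KO mRNA, −0.38 for KO translational efficiency, −0.179 for DQAD mRNA and −0.028 for DQAD footprints. Given WT mRNA level, it gave 0.187 for KO mRNA, −0.276 for KO translational efficiency, 0.058 for OE mRNA, 0.063 for OE footprints, 0.025 for OE translational efficiency, −0.169 for DQAD mRNA, −0.202 for DQAD footprints and −0.034 for DQAD translational efficiency. Not run were the reporter comparison and the 2 results over both plasmid settings (4 columns not used), the codon index and its alternatives (no coding sequences used), and leaving out the lone DQAD library of a kind. Translational efficiency has the least power: 12.6 to 31.3% of simulated 2-fold changes were recovered there, against 42.3 to 61.0% in mRNA, where no library held over 8667764 counts.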

Other observations

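The tests in this part were planned, and the genes and lists described were chosen after their values were seen. Histone genes differed in the direction of their values between the 2 kinds of library in KO. In mRNA, 2 of 11 fell and none rose, HTA2 (−0.96, SE 0.25, n = 2 per group, edgeR adjusted p = 0.0164) and HTB2 (−0.59, SE 0.18, edgeR adjusted p = 0.0266). The median was −0.29 and the list did not pass (camera adjusted p = 0.0629, and 0.02 without WT mRNA replicate 2). In footprints, 8 of 11 rose and none fell, among them HHT1 (1.04, SE 0.19, edgeR adjusted p = 0.00523) and HHF2 (0.96, SE 0.20), with a median of 0.52 (camera adjusted p = 0.0569, and called with the replicate block, 0.0186, and without WT footprint replicate 2, 0.00166). Histone genes have near-identical copies, so single members are uncertain. The mRNA decay factors, a list without DHH1, were not called in KO: 6 of 36 were higher and 5 lower in mRNA (median 0.07, camera adjusted p = 0.803), and 11 higher and 7 lower in footprints (median 0.16, camera adjusted p = 0.158).

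MET17 and HIS3 are strain markers of BY4741. MET17 (uncertain because another ORF overlaps it) stood at 19.1 CPM of mRNA and 11.9 CPM of footprints in DQAD and at 15.8 CPM of footprints in KO replicate 2; the other libraries held at most 5.77 CPM. HIS3 mRNA stood at 48.4 to 67.8 CPM in all 7 libraries, and its footprints at 78.2 and 74.2 CPM in WT, 72.8 and 75.8 CPM in KO, 160.4 and 151.1 CPM in OE and 99.3 CPM in DQAD.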
